A study of Mus musculus with 12 samples.

How the data were processed

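RNA was extracted with Trizol from female germline stem cells of C57BL/6 mice, and libraries were made with an Illumina TruSeq RNA kit, per the labels. Whether the kit or the counting kept strand is not given in the sources used here. The 12 libraries formed 4 groups of 3, as the sample titles state: Usp7 overexpression, its control, Usp7 knockdown, and its control. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm10 and GRCm38. The counting tool and the test behind the tables are not given in the sources used here.

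The authors deposited 1 table per construct, each with its own control. The library columns hold normalized counts, a signal made by the authors by dividing each transcript's reads by 1 size factor per library. The deposited tables also give a log2 fold change with its standard error, on the log2 scale, and a p-value with its adjusted p-value, all from the authors' own test. Both tables hold only transcripts that passed that test. The smallest fold in the authors' deposited tables was 1.50 in either direction and the largest adjusted p 0.0500. From the ratios of adjusted to raw p-values, about 12605 transcripts had been tested in the overexpression comparison and 12375 in the knockdown comparison. The tests made here therefore give folds and errors on a selection made from the same libraries, and their calls are not independent evidence of a change. Transcripts outside the selection, Usp7 among them, were not analysed here.

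Every value in a library column was a whole multiple of 1 step per column (100% of values, within 0.001 of a read). Whole reads were taken as recovered for 10 of the 12 columns. The other 2, both in the overexpression table, had too few low values or a step too close to 1, so count models were run on the knockdown table alone. The step gave the authors' size factors. These were 1.54, 0.915 and 0.737 for overexpression replicates 1 to 3, 0.994, 0.902 and 1.08 for its controls, 0.962, 1.28 and 0.722 for knockdown, and 1.22, 1.15 and 0.816 for its controls. Total depth per library is unknown because the tables hold part of each library. Replicate pairs with recovered reads differed by 2.03 to 37.2 in chi-square per transcript, so none was taken for 1 library deposited more than once.

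The planned test for counts was replaced because the values were normalized. Folds were fitted with limma (version 3.58.1, R 4.3.3) with a variance trend on log2(normalized count + 1), keeping the authors' scaling, for each construct against its own control. For transcripts with few reads, folds on this scale can lie on either side of the authors' folds. In overexpression Prm2 was -7.46 here and -7.91 by the authors, and Atf3 -2.53 and -2.19. Transcripts entered with a normalized count of at least 10 in at least 3 libraries and a total of at least 15. Calls used a Benjamini-Hochberg (BH) adjusted p under 0.05. Tests were made only within a table, since the tables were normalized separately. The fit was tested on simulated data with 200 changed transcripts. In the simulated overexpression table (593 transcripts tested) limma recovered 53.1% of changes of 1.5-fold, 82.3% of 2-fold and 100% of 4-fold, with 2% of calls false. In the simulated knockdown table (2955 tested) it recovered 67.7%, 90.6% and 100%, with 4.07% of calls false. The simulation used a common dispersion, left most transcripts unchanged and had no outlying library. The deposited tables hold transcripts selected as changed, so these rates do not carry over to them.

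The groups, planned tests and alternatives, gene lists and the rule for named genes were fixed before the data were examined. The 39 gene lists comprised 29 pathway lists and 10 lists of markers of other cell types. Members outside the selected tables have no value here, so all tested members of a list can be a small part of it. The list tests count genes, which are not independent replicates. For lists with at least 5 tested members, the split of called members into higher and lower was set against that of all other called genes of the table, with Fisher's exact test (two-sided) and BH adjustment over these lists. Named genes were the 8 with the highest and the 8 with the lowest log2 fold per comparison, among those with a mean of at least 100, complete separation of the 3 libraries of each group, and no predicted or clone name. To these were added up to 4 called members of each list with at least 3 measured members, and the 5 genes with the strongest opposite and the 5 with the strongest same-direction changes in both comparisons, ranked by the smaller of the 2 absolute log2 folds. Any gene or list named outside this rule is said to be chosen after its values were seen.

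Alternatives covered library scaling (median of ratios, column totals, none, and TMM), filters on low values, pseudocounts of 0.1 and 5, the variance trend, a replicate block, stricter thresholds, and leaving out each library. DESeq2 (1.42.0), edgeR (4.0.16) and voom were run on the recovered reads of the knockdown table. TMM, the fit without a variance trend and edgeR on these reads were added after the data were seen. Symbols, lengths and coordinates came from RefSeq genes on GRCm38.p6 and GENCODE M21 transcripts. RefSeq matched 643 of 648 overexpression transcripts and 3146 of 3156 knockdown transcripts, and lengths were found for 96.8% and 97.1%. Gene symbols that had been turned into dates, 1 and 5 in the respective tables, were restored from the RefSeq identifiers. Summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.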

Results

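RNA was profiled in female germline stem cells (FGSCs), cultured germ cells of the mouse ovary that can self-renew, in libraries labelled as overexpression or knockdown of Usp7, a deubiquitinase that removes ubiquitin from proteins. Each of the 4 groups (overexpression, overexpression control, knockdown, knockdown control) had 3 libraries, and each construct was compared with its own control. For overexpression 648 transcripts of 647 genes were listed, and for knockdown 3156 transcripts of 3127 genes, all selected by the authors' own test on these libraries. Listed normalized counts summed to 137282, 131157 and 155114 in overexpression replicates 1 to 3, and 128056, 135092 and 139647 in their controls. They summed to 5.38e6, 5.52e6 and 5.52e6 in knockdown replicates 1 to 3, and 3.22e6, 3.01e6 and 3.12e6 in their controls. Usp7 was not among the transcripts used here, so its level could not serve as a check of the labels.

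The first comparison asked which transcripts differed when Usp7 was overexpressed. Among the genes with the strongest changes, Piwil1 was higher and the protamine genes Prm1 and Prm2 lower. Piwil1, a PIWI protein that binds small RNAs in male germ cells, rose 11.8-fold (log2 fold 3.56 ± 0.21 SE, n = 3 per group, limma with BH adjustment, adjusted p = 4.6e-07), from 57.8 ± 7.34 to 708 ± 204 normalized counts (SD). Prm2, a protamine that packs DNA in sperm, fell 176-fold (log2 fold -7.46 ± 0.26 SE, n = 3, limma with BH adjustment, adjusted p = 9.7e-09), from 760 ± 49.5 to 3.47 ± 1.32 normalized counts (SD). The other protamine gene Prm1 (-6.26 ± 0.29 SE) and Tnp2 (-7.13 ± 0.58 SE), a transition protein that precedes protamines on sperm DNA, fell with it. Tnp2 was -6.44 without overexpression replicate 2 and -7.92 without replicate 3. Piwil1 lies at chr5:128736071-128755474 and Prm2 at chr16:10791377-10792105 (GRCm38), and both are protein-coding.

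Other strong increases in overexpression, among genes with a mean of at least 100, included Cfap65, a protein of cilia and flagella (log2 fold 3.31 ± 0.21 SE). Gzmb, a serine protease of cytotoxic lymphocytes, went from 155 ± 12.8 to 1360 ± 128 normalized counts (SD, n = 3). Hdgfl1 (3.11 ± 0.30), Mroh2a (3.06 ± 0.22) and Pabpc6 (2.97 ± 0.22) rose as well. The alpha tubulin genes Tuba3a (3.23 ± 0.20) and Tuba3b (3.03 ± 0.22) also rose, but they are near-identical copies that may share reads, so their separate values are uncertain. Among the strongest decreases at such a mean were Chac1, which degrades glutathione (-3.35 ± 0.19), and Trib3, a pseudokinase induced by ATF4 (-2.84 ± 0.15). Trib3 went from 1363 ± 43.4 to 190 ± 28.3 normalized counts (SD, n = 3). Dpysl4 (-2.63 ± 0.22), Basp1 (-2.36 ± 0.24) and the imprinted noncoding RNA Kcnq1ot1 (-2.30 ± 0.29) fell too. Kcnq1ot1 is antisense to Kcnq1, and its reads may be shared with that gene where strand was not kept.

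**Figure D1:**
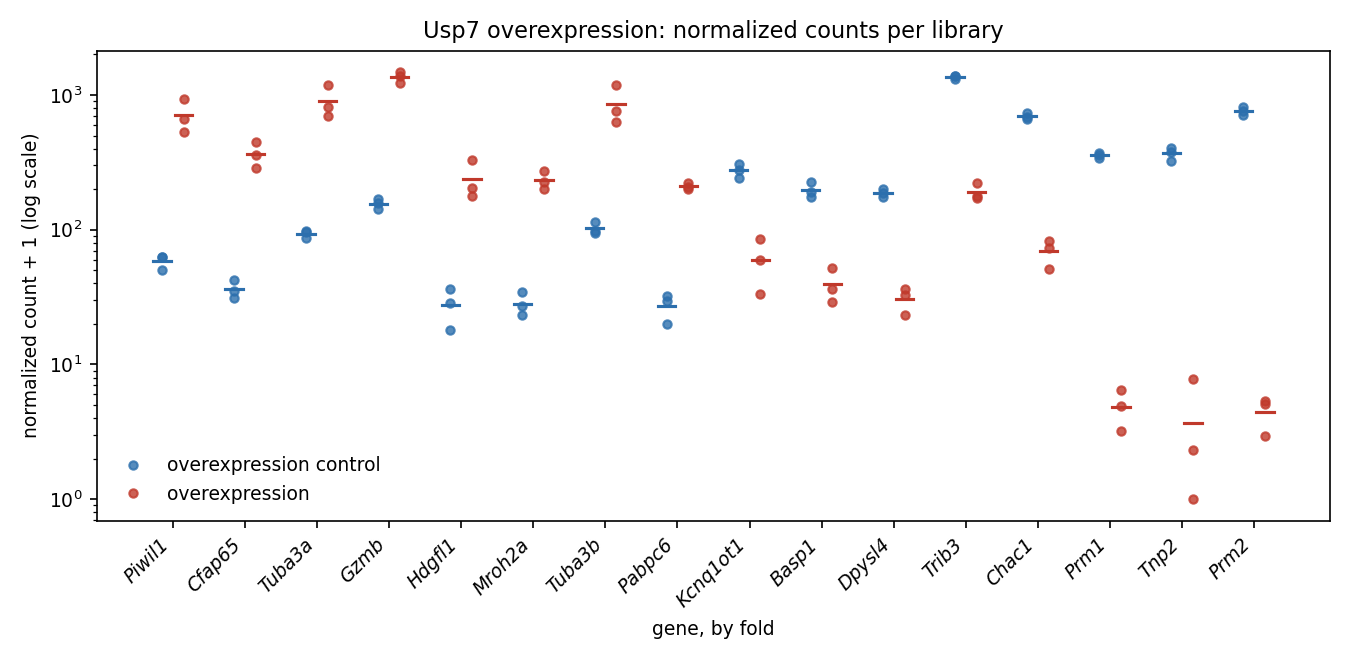
Normalized counts plus 1 (log scale) of the 16 genes with the strongest changes in Usp7 overexpression, with points for the 3 overexpression (red) and 3 control (blue) libraries and bars for group means. Piwil1 rose from a mean of 57.8 to 708, and Prm2 fell from 760 to 3.47.

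By the lists fixed beforehand, 6 of 6 tested meiosis and oocyte genes rose in overexpression (median log2 fold 2.43), among them the synaptonemal complex genes Sycp2 (2.75 ± 0.25 SE) and Syce1 (2.44 ± 0.27), the cohesin Smc1b (2.41 ± 0.25) and Meioc (2.51 ± 0.35). The list holds 33 genes, of which these 6 were in the selected table. Of the other called genes 65.0% were higher, and the list did not pass (Fisher's exact test, BH-adjusted p = 0.0977). With all 6 already higher, the test could not have passed in that direction, so it shows no lack of difference. Of 10 tested genes of the unfolded protein response and ATF4 targets, 7 fell and 3 rose (median -0.77). Atf3, a stress-induced transcription factor (-2.53 ± 0.58, and -3.33 without overexpression replicate 2), and the cystine transporter Slc7a11 (-1.61 ± 0.19) fell beside Chac1 and Trib3. The list missed the threshold (Fisher's exact test, p = 0.0373, BH-adjusted p = 0.0745). These were the 2 lists with enough members to test, and 0 of them passed, with 1 at an unadjusted p under 0.05. With median-of-ratios scaling both passed (Fisher's exact test, BH-adjusted p = 0.0484 for meiosis, with 4 of 6 genes called higher and a median of 1.22, and 0.00413 for the unfolded protein response list, with 10 of 10 genes lower), and with TMM the latter did (0.00219). All 3 tested p53 targets fell, namely Ddit4 (-1.87 ± 0.15), Pmaip1 (-1.09 ± 0.16) and Sesn2 (-0.87 ± 0.17), of which Ddit4 and Sesn2 are also induced by ATF4. All 3 glycolysis and hypoxia genes fell: Ankrd37 (-2.18 ± 0.33), Mxi1 (-1.04 ± 0.20) and Ndrg1 (-0.93 ± 0.14). Of the cell cycle list, Ccnd1 (0.74 ± 0.18) and Ccne1 (0.70 ± 0.17) rose and the inhibitor Cdkn1b (-0.69 ± 0.17) fell. The increases of both cyclins reversed under median-of-ratios scaling, to -0.50 and -0.54, and under TMM, to -0.13 and -0.16. Over all lists, 51 memberships were tested, where a gene in more than 1 list counts in each. Of these, 51 passed both over all genes and adjusted over the list alone, as did every tested transcript over all genes.

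In total, 613 of 613 tested transcripts passed in overexpression (limma, BH), 400 higher and 213 lower. In the authors' deposited table, 415 were higher and 233 lower. The share of higher calls was 65.3% with the authors' scaling, 56.8% of 498 calls with TMM and 47.0% of 477 with median-of-ratios scaling, both of which assume that most listed transcripts are unchanged.

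The second comparison asked which transcripts differed when Usp7 was knocked down. Cell cycle genes were higher, and genes of the unfolded protein response and ATF4 targets lower. Ube2c, a ubiquitin-conjugating enzyme of mitosis (chr2:164769929-164772902), rose 4.06-fold (log2 fold 2.02 ± 0.11 SE, n = 3, limma with BH adjustment, adjusted p = 4.5e-06), from 476 ± 28.7 to 1946 ± 240 normalized counts (SD). Trib3 (chr2:152337425-152344060) fell 24.5-fold (log2 fold -4.61 ± 0.09 SE, n = 3, limma with BH adjustment, adjusted p = 2.0e-08), from 5049 ± 215 to 206 ± 15.1 normalized counts (SD). The stress-induced chromatin protein Nupr1 fell from 308 ± 27.0 to 8.92 ± 3.08 normalized counts (SD, n = 3; log2 fold -5.00 ± 0.22 SE).

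Further genes with strong increases in knockdown were the histone gene Hist2h2bb (log2 fold 3.01 ± 0.21 SE), the aldo-keto reductase Akr1c13 (2.63 ± 0.17), the Wnt receptor Fzd9 (2.49 ± 0.14), the metallothionein Mt2 (2.26 ± 0.15), Spint1 (2.15 ± 0.12), Onecut3 (2.11 ± 0.12) and the cyclin Ccnf (2.03 ± 0.11). Strong decreases included the heat shock gene Hspa1a (-4.36 ± 0.11), the protease Ctsg (-4.19 ± 0.30), Chac1 (-4.06 ± 0.12), Pi16 (-3.86 ± 0.27), Tcp11l2 (-3.46 ± 0.19) and Angptl6 (-3.33 ± 0.16). Hspa1a has the near-identical copy Hspa1b (-2.97 ± 0.14), and Hist2h2bb belongs to a multigene family, so their separate values are uncertain.

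**Figure D2:**
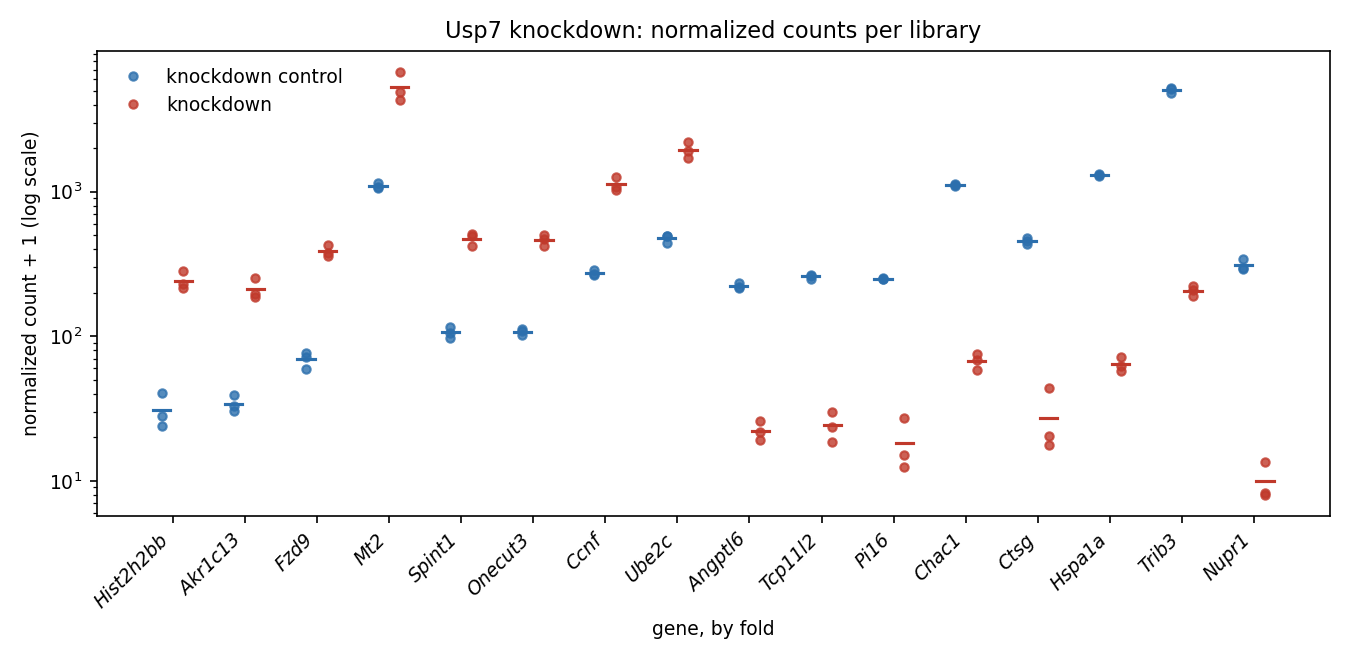
Normalized counts plus 1 (log scale) of the 16 genes with the strongest changes in Usp7 knockdown, with points for the 3 knockdown (red) and 3 control (blue) libraries and bars for group means. Ube2c rose from a mean of 476 to 1946, and Trib3 fell from 5049 to 206.

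Of the 39 lists, 22 had enough members to test in the knockdown table, and 8 passed (Fisher's exact test, BH-adjusted). Of these 8, 4 had most or all tested members higher and 4 most or all lower. Tested were 27 of 79 ribosomal protein, 25 of 74 oxidative phosphorylation, 25 of 43 histone and 28 of 64 cell cycle genes. Among the lists that were lower, they were 23 of 75 matrix, 14 of 40 unfolded protein response, 8 of 22 immediate early and 7 of 33 meiosis genes. With column totals as the scaling, which lowered most folds, 3 passed, namely the cell cycle list (10 of 28 genes called higher, median 0.17), the histone list (19 of 25, median 1.27) and the oxidative phosphorylation list (6 of 25, median 0.21). With no scaling 6 passed, and the meiosis and immediate early lists did not. Of the cell cycle and replication list, 27 genes rose and 1 fell (median log2 fold 0.98; Fisher's exact test, BH-adjusted p = 3.69e-07). Its strongest members after Ube2c were the cyclin genes Ccnb1 (1.92 ± 0.09 SE) and Ccne1 (1.87 ± 0.11), and the mitotic kinase gene Cdk1 (1.84 ± 0.10). All 25 tested histone genes rose (median 2.01; Fisher's exact test, BH-adjusted p = 1.29e-07), including Hist1h2ag (2.86 ± 0.33) and Hist1h2ak (2.51 ± 0.19). All 25 oxidative phosphorylation genes rose (median 1.02; Fisher's exact test, BH-adjusted p = 1.29e-07), including Sdhd (1.72 ± 0.09), Atp5l (1.67 ± 0.23), Cox7a2 (1.40 ± 0.22) and Uqcrh (1.38 ± 0.14). All 27 cytosolic ribosomal protein genes rose with the authors' scaling (median 0.79; Fisher's exact test, BH-adjusted p = 9.16e-08), but their median was -0.03 when libraries were scaled to column totals. Rpl39 (1.47 ± 0.31) and Rps24 (1.38 ± 0.19) led this list, whose genes have many processed copies in the genome. The ribosomal RNA precursor Rn45s, chosen after its values were seen, was higher (log2 fold 1.06 ± 0.17 SE), though not past the threshold under column totals, which it dominates. It made up 65.3%, 63.8% and 58.7% of listed counts in knockdown replicates 1 to 3, and 52.8%, 51.5% and 53.6% in the controls. Whether this reflects ribosome production or the amount of ribosomal RNA kept in each library was not tested.

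All 14 tested genes of the unfolded protein response and ATF4 targets fell in knockdown (median log2 fold -1.60; Fisher's exact test, BH-adjusted p = 4.45e-04). Atf3 fell most, by 6.10 on the log2 scale (± 0.37 SE), followed by Nupr1, Trib3 and Chac1. All 8 immediate early genes, which answer growth and stress signals within minutes, fell (median -1.22; Fisher's exact test, BH-adjusted p = 0.0245), including Btg1 (-2.45 ± 0.17), Jun (-1.56 ± 0.13), Dusp1 (-1.35 ± 0.20) and Fos (-1.32 ± 0.25). All 7 meiosis and oocyte genes fell (median -1.26; Fisher's exact test, BH-adjusted p = 0.0429), including Syce1 (-1.43 ± 0.11), Smc1b (-1.34 ± 0.18), Stra8 (-1.30 ± 0.33) and Sycp2 (-1.26 ± 0.25). The germ cell list had 4 tested genes, too few for its test, and all fell: Tex101 (-1.48 ± 0.12), Mael (-1.16 ± 0.13), Id4 (-1.05 ± 0.21) and Foxo3 (-0.74 ± 0.09).

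Of the extracellular matrix genes, 22 fell in knockdown and 1 rose (median log2 fold -2.01; Fisher's exact test, BH-adjusted p = 2.48e-05). Knockdown control replicate 2 stood apart here: 172 listed transcripts lay over 2 log2 units above both other controls in that library, and 171 of them were lower in knockdown. Col1a1, a fibrillar collagen, had 170, 735 and 185 normalized counts in control replicates 1 to 3 and 43.7, 49.9 and 69.3 in the knockdown replicates. Without that control library, 22 matrix genes were still lower and 1 higher, with a median of -1.48. The log2 fold then changed from -3.28 to -2.42 for Col5a1, from -2.62 to -1.70 for Lamb1, from -2.46 to -1.48 for Nid1 and from -2.46 to -1.97 for Timp2. The marker lists of stromal cells did not pass, with 6 of 7 listed smooth muscle markers and 5 of 9 listed fibroblast markers tested. Of 6 smooth muscle and contractile markers, 5 fell and 1 did not pass (Fisher's exact test, BH-adjusted p = 0.145), and 3 fell without control replicate 2. With 0 of the smooth muscle markers higher and so few called, the test could not have passed in that direction. Of 5 fibroblast and feeder cell markers, 3 fell and 2 rose (Fisher's exact test, BH-adjusted p = 1), and the list shares 8 genes with the matrix list.

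**Figure D3:**
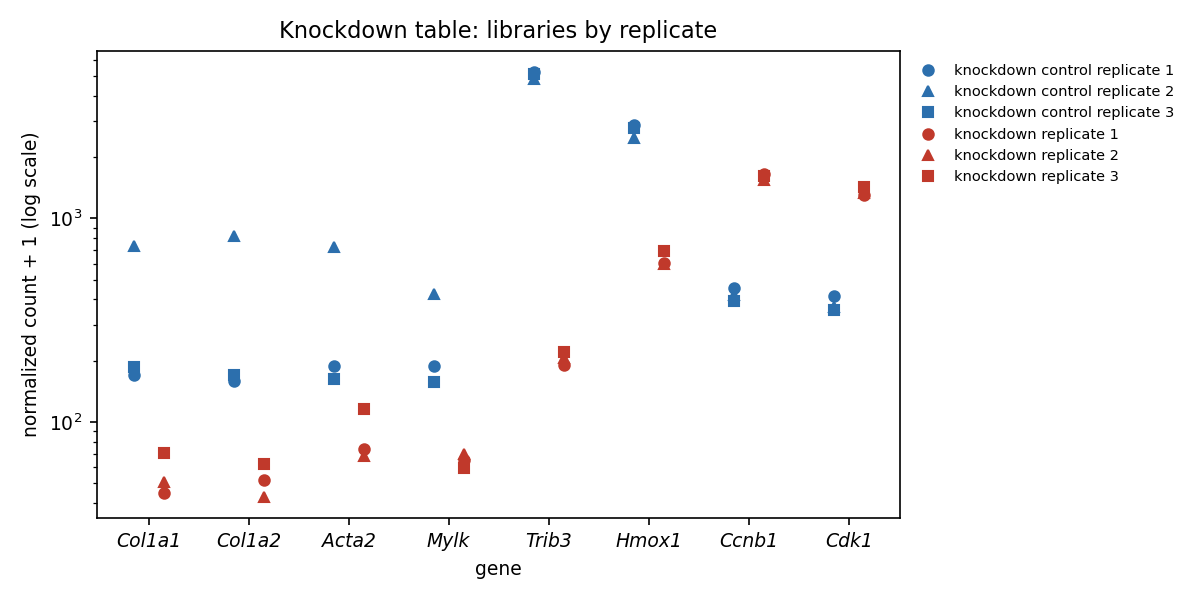
Normalized counts plus 1 (log scale) of 8 genes in each of the 6 libraries of the knockdown table, with color for group and symbol for replicate. Col1a1, Col1a2, Acta2 and Mylk were higher in knockdown control replicate 2 than in the other controls, with Col1a1 at 735 against 170 and 185, whereas Trib3, Hmox1, Ccnb1 and Cdk1 were not.

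The remaining lists named here either did not pass in knockdown or had fewer than 5 tested members. Of the p53 targets, 7 fell, among them Gadd45a (-3.09 ± 0.21 SE), Ddit4 (-2.63 ± 0.13) and Bbc3 (-1.77 ± 0.21), and 2 rose (Fisher's exact test, BH-adjusted p = 0.329). Of the DNA damage and repair genes, 6 rose, including Pcna (0.96 ± 0.10) and Exo1 (0.86 ± 0.12), and 1 fell (Fisher's exact test, BH-adjusted p = 0.145), with a median that turned negative under column totals. Of the oxidative stress genes, 6 rose and 5 fell, with Mt2 higher and the heme oxygenase Hmox1 lower (-2.10 ± 0.10), and the median, above 0 here, also turned negative under column totals. Of the cholesterol and lipid synthesis genes, 4 rose, including the fatty acid synthase Fasn (1.36 ± 0.10), and 3 fell. Glycolysis and hypoxia genes comprised 5 that rose, such as Egln3 (1.26 ± 0.09), and 2 that fell, such as Ndrg1 (-2.76 ± 0.09). In the Notch list 4 rose and 2 fell (a median above 0 that turned negative under column totals), in the Wnt list 3 rose and 4 fell, and in the TGF-beta and BMP list 1 rose and 4 fell. Interferon genes had 5 higher and 1 lower, again with a median that turned negative under column totals. Heat shock genes had 1 higher and 4 lower, apoptosis genes 4 higher and 2 lower, and inflammation genes 3 in each direction and 1 that did not pass. Among other ubiquitin-specific proteases, too few for the test, Usp46 (1.02 ± 0.17) and Usp18 (0.91 ± 0.18) rose and Usp2 (-0.89 ± 0.15) and Usp32 (-0.69 ± 0.15) fell. Usp26, outside the list and chosen after its values were seen, also fell (-1.86 ± 0.32). Of the Polycomb and chromatin partners of Usp7, also not tested as a list, Cbx6 (0.94 ± 0.10) and Pcgf3 (0.60 ± 0.12) rose and Ring1 (-0.59 ± 0.15) fell, with Pcgf3 at -0.21 under column totals. Of the methylation enzymes, not tested as a list either, the histone demethylases Kdm5b (-0.92 ± 0.09), Kdm6b (-0.89 ± 0.11) and Kdm4a (-0.59 ± 0.12) fell.

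**Figure D4:**
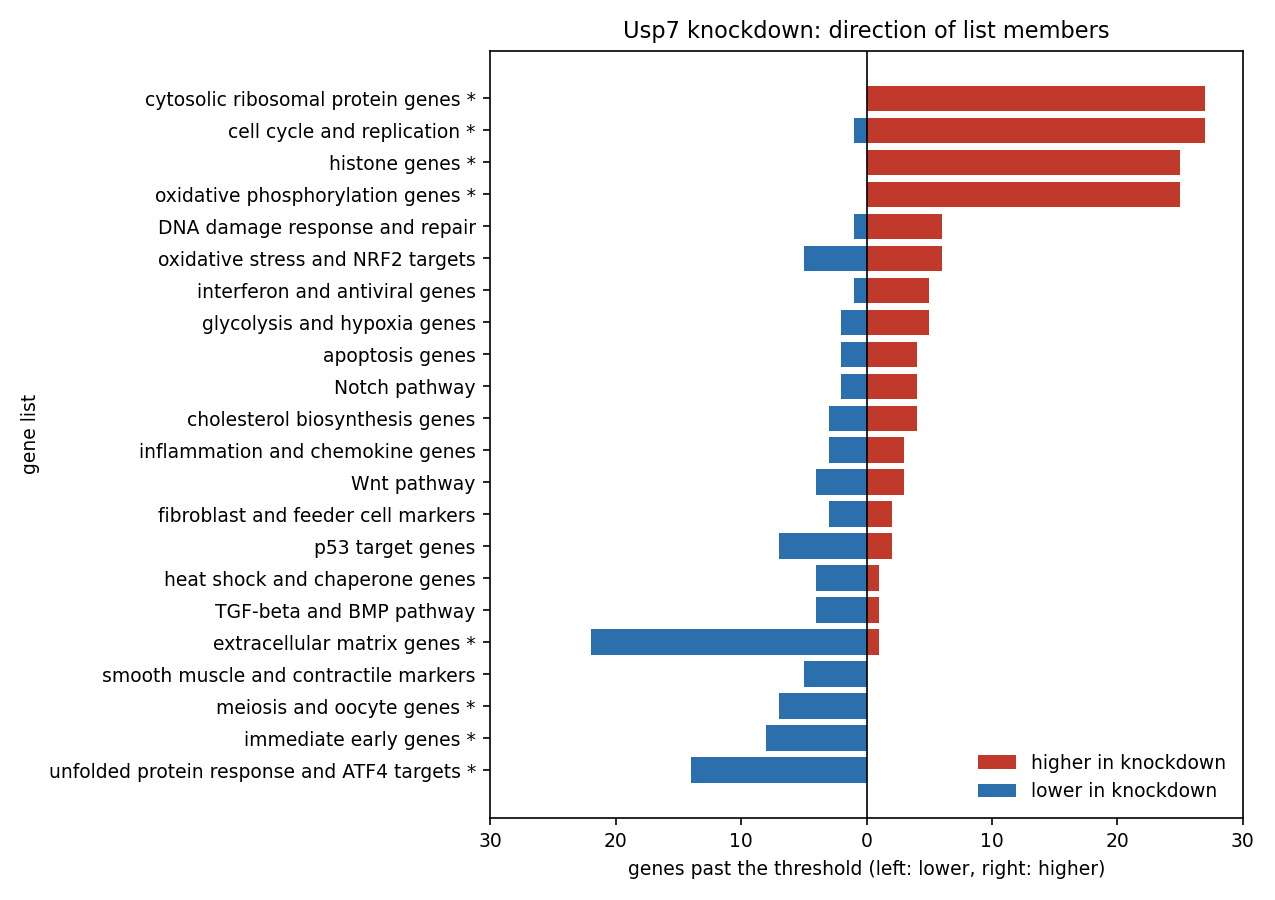
Number of called genes higher (right, red) and lower (left, blue) in Usp7 knockdown for each of the 22 lists tested, with an asterisk where Fisher's exact test passed after BH adjustment. The ribosomal protein list had 27 genes higher and 0 lower (median -0.03 under column totals), and the matrix list had 1 higher and 22 lower.

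In total, 2898 of 2902 tested transcripts passed in knockdown (limma, BH), 1426 higher and 1472 lower. Of 290 tested list memberships, counted as in overexpression, 288 passed, and 287 passed when adjusted over the list alone. In the authors' deposited table, 1446 were higher and 1710 lower. The share of higher calls was 49.2% with the authors' scaling and 15.3% of 1757 calls with column totals. It was 32.6% of 2143 calls with no library scaling.

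The third comparison asked whether the opposite manipulations moved shared genes in opposite directions. Most shared genes were lower in knockdown, whichever way they had moved in overexpression. Of 436 transcripts past the threshold in both comparisons, 318 were higher in overexpression and lower in knockdown, 75 lower in both, 36 higher in both, and 7 lower in overexpression and higher in knockdown. By the smaller of the 2 absolute folds, the strongest opposite changes were those of Gcnt3 (log2 fold 3.25 ± 0.59 SE in overexpression, -2.0 ± 0.25 in knockdown, n = 3 per group), the cytolinker Eppk1 (3.06 ± 0.45 and -1.86 ± 0.29), the flagellar radial spoke gene Rsph6a (3.29 ± 0.48 and -1.83 ± 0.15), the phosphate transporter Slc34a2 (2.34 ± 0.37 and -1.81 ± 0.20) and Chgb (2.80 ± 0.54 and -1.77 ± 0.22). No minimum mean applied to this ranking. In the order named, the overexpression controls of these genes averaged 1.34, 3.25, 6.59, 5.26 and 2.27 normalized counts, so their overexpression folds rest on few control reads. Gcnt3 was 4.02 without overexpression control replicate 1, and Chgb 2.09 without replicate 2 of that group. By the same measure, the strongest changes in the same direction were those of Atf3 (-2.53, or -3.33 without overexpression replicate 2, and -6.10), Trib3 (-2.84 and -4.61), Chac1 (-3.35 and -4.06), Spz1 (-3.12 ± 0.30 and -2.47 ± 0.38) and Hspa1a (-2.21 ± 0.33 and -4.36 ± 0.11).

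Of the 354 shared transcripts higher in overexpression, 89.8% were lower in knockdown, and of the 82 lower in overexpression, 91.5% were. These shares did not differ (odds ratio 1.21, Fisher's exact test, two-sided, p = 0.837). The odds ratio fell to 0.143 with TMM and 0.0143 with median-of-ratios scaling, so the direction of this relation depends on the scaling of the selected transcripts. Independent lists of these sizes would share 46.7 transcripts higher in overexpression and lower in knockdown, 24.9 lower in both, 45.3 higher in both and 24.1 lower in overexpression and higher in knockdown, over 12605 transcripts. The comparisons share no control library.

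**Figure D5:**
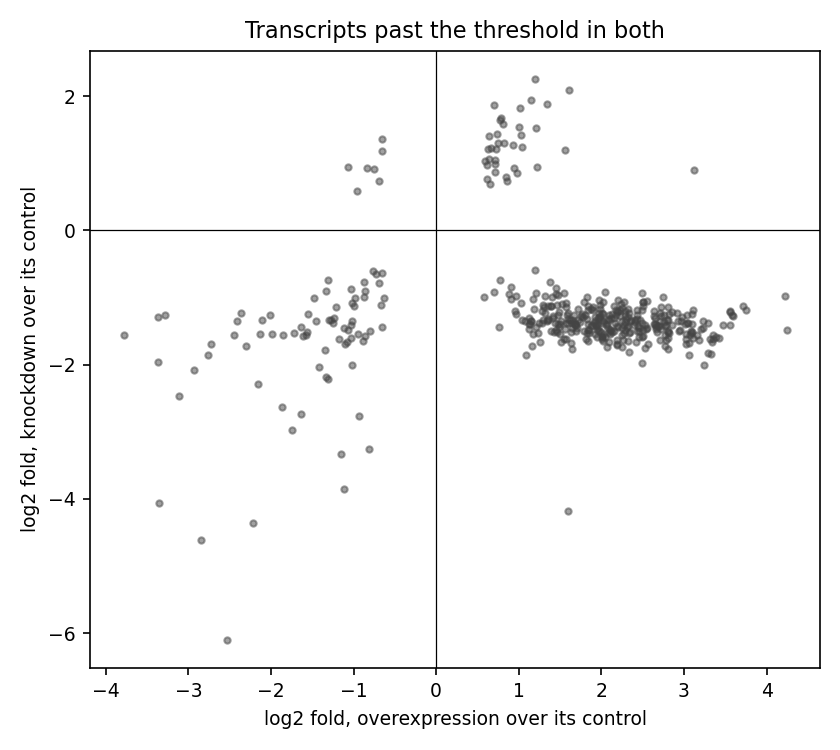
Log2 fold in Usp7 overexpression (x axis) against log2 fold in Usp7 knockdown (y axis), each over its own control, with 1 point per transcript past the threshold in both (436). The lower right area holds 318 transcripts and the lower left 75.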

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

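The tests of both explanations in this part, and Dnah8 as an example, were chosen after the result was seen. For 325 of the 436 transcripts past the threshold in both comparisons, all 3 overexpression libraries lay on one side of their controls and all 3 knockdown libraries on the other side of theirs. This stood out as a difference between groups, and the difference itself was not tested, because the tables were normalized separately. The 318 transcripts higher in overexpression and lower in knockdown, which include Piwil1 (3.56 ± 0.21 and -1.41 ± 0.14 SE) and the outer dynein arm gene Dnah8 (2.15 ± 0.17 and -1.49 ± 0.10), make up nearly the whole set.

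A carried-over pool of testis-type RNA in varying amounts, as an explanation for these 318, would move sperm chromatin and meiosis genes the same way. In overexpression their medians lay on opposite sides of 0 (difference in log2 fold -8.27, medians -5.84 over 7 genes and 2.43 over 6). The sperm chromatin list was chosen after its values were seen, and 0 of its genes were listed in knockdown. These values therefore cannot decide for the 318, and carry-over stays open. Different starting levels in the control groups stay open as a candidate explanation: across separately normalized tables, the knockdown controls lay a median of 3.49 log2 units above the overexpression controls (quartiles 2.97 and 4.07). The overexpression and knockdown libraries differed by a median of -0.05 (quartiles -0.19 and 0.12). Picking transcripts for opposite changes requires a gap between the controls, between the overexpression and knockdown libraries, or both. The selection alone does not set which of these it is. An effect of Usp7 in both directions from controls that differed, and mislabelled libraries, also stay open and untested, since the level of Usp7 was not analysed here.

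Over the 448 transcripts listed in both tables, which were normalized separately, overexpression libraries differed from knockdown libraries by median absolute gaps of 0.20 to 0.47 log2 units, and from each other by 0.30 to 0.44. The gaps were 1.66 to 2.15 between overexpression and its controls, 1.25 to 1.49 between knockdown and its controls, and 2.94 to 3.29 between the control groups. These transcripts had been selected as changed in both comparisons, so the gaps between each construct and its own controls are partly built in. The gap between the control groups can follow from these, but the selection alone does not fix it. None of these gaps describes transcripts outside the selection.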

How the results depend on the processing

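TMM scaling, the fit without a variance trend and edgeR were chosen after seeing the data, and the other alternatives before. The tables hold selected transcripts, so agreement between settings says little about the genes outside them, and total depth is unknown. In overexpression, TMM moved the median log2 fold of all tested transcripts by -0.85, median-of-ratios by -1.21 and column totals by -0.07. In knockdown the shifts were -0.13, 0.15 and -0.81, and -0.12 with no scaling. Both TMM and median-of-ratios assume that most listed transcripts are unchanged, which a selected table does not meet.

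The overexpression count of 613 was between 331 (mean of at least 50, where fewer were tested) and 648 under all alternatives run, with 224 higher and 253 lower of 477 under median-of-ratios and 283 higher and 215 lower of 498 under TMM. The knockdown count of 2898 fell to 1757 (268 higher, 1489 lower) with column totals and to 1613 (477 higher, 1136 lower) at an absolute log2 fold of at least 1. It was 2143 (699 higher, 1444 lower) with no scaling, 2126 (1281 higher, 845 lower, 60.3% higher) at a mean of at least 50, 2902 with DESeq2 and with edgeR, and 2881 with voom. Leaving out single libraries gave 620 to 623 calls in overexpression and 2912 to 2968 in knockdown. The number of lists past the threshold in overexpression (0) was 2 under median-of-ratios and 1 under TMM and at an absolute log2 fold of at least 1, and 0 without any single library. In knockdown (8) it was 3 with column totals and 5 at an absolute log2 fold of at least 1, and 8 to 9 without single libraries. With no scaling it was 6, without the meiosis and immediate early lists. The cause was not tested beyond the shifts above.

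The odds ratio between directions (1.21) reversed to 0.0143 (Fisher's exact p = 5.97e-13) under median-of-ratios and 0.143 (p = 6.42e-03) under TMM, was 4.01 (p = 0.217) with column totals, and lay between 1.20 and 1.43 without single libraries. At an absolute log2 fold of at least 1 a cell of 0 gave no odds ratio. In overexpression, Ccnd1 and Ccne1 reversed to -0.50 and -0.54 under median-of-ratios and to -0.13 and -0.16 under TMM. In knockdown, Clspn (-0.048), Pcgf3 (-0.21), Dusp6 (-0.22) and Fcgr1 (-0.20) reversed under column totals. The shifts of scaling account for these. Of 636 values of 38 named genes in overexpression, 627 kept direction and call, 5 lost the call and 4 reversed. Of 2691 values of 130 genes in knockdown, the numbers were 2616, 71 and 4. Serping1, Actg2, Atr and Smad1 lost the call in knockdown without single libraries, Actg2 and Smad1 without control replicate 2.

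With the replicate number as a block, 613 and 2898 transcripts passed. Replicates sharing a number did not deviate together (correlations -0.04, -0.11 and 0.05 in overexpression, and -0.07, -0.02 and -0.10 in knockdown). These values gave no sign that the numbers pair the libraries, but with 3 libraries per group they cannot exclude pairing. Among named genes, Actg2 alone lost the call in that fit. No scaling, DESeq2 and voom were not run in overexpression, because reads were not recovered for all of its libraries.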

Other observations

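The comparison of stromal excesses and the other splits of the libraries were set down before their results were seen. The gene lists and genes of the next paragraphs, and all other tests in this part, were chosen after. Fisher's exact tests of lists chosen after were BH-adjusted over those lists alone, without the fixed lists. Such lists were picked from the values they are tested on, so their p-values are no independent evidence.

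In overexpression, 40 of 41 genes of the axoneme and sperm flagellum families rose and 1 fell (median log2 fold 2.19; Fisher's exact test, BH-adjusted p = 1.06e-06). With median-of-ratios scaling 29 were called higher (median 0.97), and with TMM 35 (median 1.34). The family members included the dynein heavy chains Dnah8 (2.15 ± 0.17 SE) and Dnah17 (2.39 ± 0.18). All 4 genes of PIWI and transposon silencing rose (median 3.27), including Tdrd9 (3.35 ± 0.24) and Mov10l1 (3.18 ± 0.27), as did the meiotic cohesin Stag3 (2.24 ± 0.21) and the germ cell lactate dehydrogenase Ldhc (1.87 ± 0.15). In contrast, all 7 sperm chromatin packaging genes fell (median -5.84; Fisher's exact test, BH-adjusted p = 5.6e-04), including the linker histone H1fnt (-3.69 ± 0.46), and so did the sperm tail and mitochondrial sheath genes Odf1 (-2.73 ± 0.24) and Smcp (-3.29 ± 0.24). Odf1 and Smcp lie outside the axoneme and flagellum list, whose lowest member was at -1.89. That list therefore does not cover all flagellum genes. The abundant nuclear RNA Malat1 fell from 30082 ± 2732 to 12686 ± 2349 normalized counts (SD, n = 3; log2 fold -1.26 ± 0.20 SE).

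In knockdown, 49 of 50 axoneme and flagellum genes fell and 1 rose (median log2 fold -1.39; Fisher's exact test, BH-adjusted p = 5.7e-13), and all 8 PIWI and transposon silencing genes fell (median -1.54; Fisher's exact test, BH-adjusted p = 0.0091, but 0.719 under column totals and 0.0699 with no scaling). All 30 mitochondrial ribosomal protein genes rose (median 0.87; Fisher's exact test, BH-adjusted p = 1.12e-09), but 7 were called higher under column totals (median 0.064) and 15 with no scaling (median 0.75). All 20 proteasome subunit genes rose with the authors' scaling (median 0.79; Fisher's exact test, BH-adjusted p = 1.11e-06). Under column totals 2 were higher and 1 lower past the threshold, the median was -0.02, and the list did not pass (Fisher's exact test, BH-adjusted p = 0.0876). All 5 aminoacyl-tRNA synthetase genes, which ATF4 induces, fell (median -1.0; Fisher's exact test, BH-adjusted p = 0.0625, past no threshold). The metallothionein genes Mt1 and Mt2 rose by 1.58 ± 0.14 and 2.26 ± 0.15 in knockdown, and by 0.80 ± 0.19 and 1.20 ± 0.21 in overexpression, where their median turned to -0.24 under median-of-ratios scaling. Ctsg rose in overexpression (1.59 ± 0.24, not past the threshold under median-of-ratios scaling) and fell in knockdown (-4.19 ± 0.30). Of the 436 transcripts called in both comparisons, 90.1% were lower in knockdown, against 43.8% of the 2462 called in knockdown alone (odds ratio 11.7, Fisher's exact test, p = 5.7e-80). The transcripts are not independent replicates, so this p-value does not measure the spread between libraries.

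Extracellular matrix genes were lower in knockdown, and knockdown control replicate 2 held an excess of them. Without that library, 22 members were still lower and past the threshold, so its excess was not the whole difference for them. The median fold of those 22 shrank from 4.08 to 2.79 (log2 -2.03 to -1.48, upper quartile -1.26). Passing is no independent evidence, since the members had been selected with that library included and 2912 of 2931 tested transcripts passed without it. Of 31 listed matrix genes 23 were tested, so excess stromal RNA in that library stays open for the rest. A smaller share of stromal cells in the knockdown libraries cannot be told apart from other causes. The excess of control replicate 2 over control replicate 3 and that of control replicate 1 over knockdown replicate 1 had a Spearman's rho of 0.0739 across 33 stromal genes (95% bootstrap interval -0.352 to 0.468), which are not independent replicates. An effect of Usp7 on matrix genes stays open and was not tested separately.

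Abundant and short transcripts were more often higher in knockdown: the log2 fold had a Spearman's rho of 0.45 with the authors' mean across 2902 transcripts, which are not independent replicates, and in 5 classes of length from shortest to longest 66.3%, 51.3%, 45.4%, 49.4% and 34.6% were higher. A trend with length cannot be told apart from the other causes: without the 65 ribosomal protein, oxidative phosphorylation and histone transcripts, lists taken up because their members were higher, 61.9% of the 498 others in the shortest class (up to 1347 nt) were still higher. More RNA without a poly(A) tail in the knockdown libraries and a larger share of cycling cells also stay open. The lists behind the first were taken up because they were higher, and the second was prompted by the cell cycle list itself. The tests run for them therefore cannot decide. The ribosomal RNA precursor Rn45s, also chosen after its values were seen, was higher as well (log2 fold 1.06 ± 0.17 SE) and entered neither test. The 56 replication-dependent histones and small nucleolar RNAs had a median log2 fold of 1.97, which is 0.98 above that of 28 cell cycle genes (permutation test, p = 2e-05). These cell cycle genes had a median of 0.98, and 27 of them were higher (Fisher's exact test, BH-adjusted p = 3.69e-07). Histones belong to both explanations, and an effect of Usp7 itself was not tested apart from them.

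For each comparison, 1 of 10 splits of its 6 libraries into 3 and 3, the real one, gave as many calls by limma, with 613 in overexpression and 2898 in knockdown. The highest of the other splits gave 0 in both. At an unadjusted p under 0.05, the other splits gave 4 to 12 transcripts in overexpression and 7 to 31 in knockdown. With 10 splits the share cannot go under 0.05, and the transcripts had been selected on the real split.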
